A study of Homo sapiens with 4 samples.

How the data were processed

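RNA from MDA-MB231 and Hs578T cells, each as a control and as FBP1-expressing stable clones, was measured on Affymetrix arrays, 1 array per combination. Per the labels' protocols, total RNA came from cells harvested in log-phase growth in culture medium with serum. Samples were grouped by the line and construct given in the labels. The table deposited by the authors held log2 expression values of 33297 probe sets. Per the submitters' processing notes, Affymetrix Expression Console version 1.1.2800.28061 was used. The normalization and summarization method is not given in the sources used here. The log2 scale was taken from the values, which ran from 2.40 to 14.81. The arrays had near-equal medians; where arrays are scaled to each other, a change in the total RNA of a cell is hidden.

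Probe sets were named through the platform annotation. A single gene was listed for 19460 probe sets, several for 1754 and none for 12083. Probe sets with several genes or none entered no gene result, and were fitted only in an alternative that counts probe sets. Of the single-gene probe sets, 19429 matched a current Entrez gene, and 0 symbols needed updating. For a gene with several probe sets, the one with the highest mean over the 4 arrays was taken, which left 18417 genes. Genes whose mean lay below the 25th percentile of probe set means (log2 6.16) were left out, and 15946 were tested. Genes with similar copies, such as histones, protocadherins, AKR1C genes and small nucleolar RNAs, are uncertain because probes can bind several of them.

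Within a line, 1 array per group allows no test. Changes are FBP1 minus control on the log2 scale, and genes were counted by size, at 2-fold and at 1.5-fold. The overlap between lines was set against that of independent lists, and the lines share no control. Both lines together were fitted with limma 3.58.1 in R 4.3.3 with terms for cell line and construct and a variance prior with an intensity trend. The cell line is the block that pairs each FBP1 array with its control. This leaves 1 residual degree of freedom, moderated by a prior of 5.04 degrees of freedom. The difference between lines is a coefficient of the same fit. Adjusted p-values are Benjamini-Hochberg, called at 0.05.

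The 38 gene lists of pathways, transcriptional programmes and cell type markers were fixed before the data were examined, as were the tests and the rule for named genes. For each line, a list's median change was set against 10000 random lists of the same size matched on mean expression in 20 bins, and called outside when beyond the central 95% range. This describes the arrays and is not a test over replicates. Over both lines, limma's camera with a preset correlation of 0.01 was run, with an estimated correlation and fry as alternatives. The preset run rests on the spread over genes, not over replicates, and assumes that low correlation for every list. The estimated run rests on the 1 residual degree of freedom and could hardly call any list, so its large p-values decide nothing.

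Named genes were FBP1, up to 15 each way of those changed alike by at least 1.5-fold in both lines, the 8 largest changes each way per line, up to 5 each way of those changed at least 2-fold in opposite directions, up to 4 members per list with the largest mean change, members of the epithelial-mesenchymal and FBP1 lists as needed, and the 12 largest called differences each way between lines. Near-identical family members could be counted in place of being named.

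On simulated data with the 15946 genes and 50 changed genes per size, the fit over both lines recovered 10% of log2 changes of 0.5, 94% of changes of 1 and 100% of changes of 2 and 4, with 12 false calls beside 152 true ones. The simulated changes were equal in both lines. All sizes were simulated together, and many changed genes loosen the cutoff of the adjusted p. Where few genes change alike in both lines, recovery is lower than these percentages. Of 199 unshifted simulated lists, 6.03% lay outside the matched range. The simulated noise was independent between genes, so this does not cover lists whose members vary together. Alternatives covered the probe set filter, quantile normalization, median centring, the variance prior, averaging of probe sets, unnamed probe sets, the block, the size threshold and the lists' correlation. Additional alternatives were chosen after the data were seen and are named as such.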

Results

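Gene expression was measured in MDA-MB231 and Hs578T, established human cell lines that the labels class as basal-like breast cancer. FBP1, which encodes the gluconeogenic enzyme fructose-1,6-bisphosphatase, was expressed in each line and stable clones were selected. Each line gave 1 control array and 1 FBP1 array, so the 4 arrays formed 4 groups of 1. Median log2 intensity over all probe sets was 7.86 in the MDA-MB231 control, 7.85 in MDA-MB231 with FBP1, 7.83 in the Hs578T control and 7.84 in Hs578T with FBP1. Across probe sets, the arrays of a line correlated at r = 0.9962 in MDA-MB231 and r = 0.9942 in Hs578T, and arrays of different lines at 0.9613 to 0.9637. Probe sets are not independent replicates. A difference within a line had no replicate check, and the small number of arrays limited the precision of every value.

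The introduced gene was examined first, because it checks the labels. FBP1 was higher in the FBP1 array of each line. Its log2 intensity was 9.83 in the MDA-MB231 control and 13.07 with FBP1, which is 9.44-fold higher. In Hs578T it was 6.35 in the control and 13.35 with FBP1, which is 128-fold higher. The Hs578T control value lies close to the filter level of 6.16 and was not shown to be above background, so the sizes of folds that rest on it are uncertain. The FBP1 arrays of the lines differed by 1.21-fold, whereas the control arrays differed by 11.2-fold, with MDA-MB231 the higher. The limma fit over both lines gave a mean log2 change of 5.12 with a standard error of 0.77 and an adjusted p of 0.943.

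**Figure D1:**
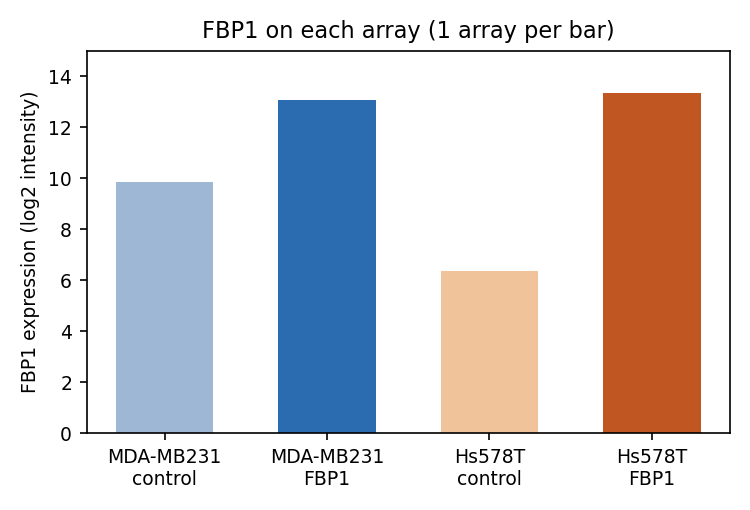
FBP1 expression (log2 intensity, vertical axis from 0) on each of the 4 arrays, 1 array per bar and so without error bars. The FBP1 arrays stand at 13.07 and 13.35, and the control arrays at 9.83 in MDA-MB231 and 6.35 in Hs578T.

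The next question was which other transcripts differed between FBP1-expressing and control MDA-MB231 cells. Besides FBP1, the genes with the largest increases were the histone genes H2BC7 (log2 change 1.81) and H4C5 (1.80), NETO2 (1.61), a kainate receptor auxiliary subunit, and AMOT (1.45), an angiomotin that binds YAP. KLHL9 (2.15-fold), the smooth muscle actin-binding gene TAGLN (1.02) and the fatty acyl-CoA reductase gene FAR2 (0.99) followed. The largest decreases were in the organic anion transporter gene SLCO4C1 (−1.51), PAGE5 (−1.27), the matrix proteoglycan gene LUM (−1.13) and HLA-DMB (−0.94), which acts in class II peptide loading. HMGCS1 (−0.90) and INSIG1 (−0.86), both sterol-regulated, the interferon-induced RSAD2 (−0.88) and the complement factor gene CFI (−0.87) completed the 8 largest decreases. At least 2-fold differences were few, with 7 genes higher and 3 lower of 15946. Of all genes, 99.37% lay within 1.5-fold of control. H2BC7, H4C5, NETO2 and KLHL9 were dim in the MDA-MB231 control (5.14, 5.75, 5.80 and 5.51 log2) and bright in the Hs578T control (12.03, 11.98, 12.70 and 11.19 log2). At the control levels of H2BC7, H4C5, NETO2 and KLHL9, 19 genes, these 4 included, were at least 16-fold more abundant in Hs578T. Of the 19, 18 were above control, with a median change of 0.35, against 0.02 for 964 other genes at these levels. Without the 4, which were picked for their increase, 14 of 15 were above control, with a median of 0.267. Without genes at least 16-fold more abundant in Hs578T, an alternative added after the data were seen, 3 genes were at least 2-fold higher. Histone genes are near-identical in sequence, so the values of H2BC7 and H4C5 are uncertain.

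The same question in Hs578T gave more and larger differences, with 46 genes at least 2-fold higher and 73 at least 2-fold lower, and 96.92% of genes within 1.5-fold. After FBP1 the largest increases were in the aldehyde oxidase gene AOX1 (1.96), the immune receptor gene SLAMF7 (1.69), the chemerin receptor gene CMKLR1 (1.58), LINC00670 (1.53), SLCO4C1 (1.53), UG0898H09 (1.52) and MAL2 (2.84-fold). The largest decreases were in the secreted Wnt modulator SFRP2 (−2.56), the pseudogene NMRAL2P (−2.37) and TXNIP (−2.37), a glucose-responsive thioredoxin-binding protein. KCNE4 (−1.89), a potassium channel subunit, ADAM23 (−1.80), the butyrylcholinesterase gene BCHE (−1.75), the protocadherin gene PCDHB6 (−1.69) and the cystatin gene CSTA (−1.67) followed. PCDHB6 belongs to a family of similar sequences and its value is uncertain. With probe sets below the 50th percentile of mean intensity left out, 43 genes were at least 2-fold lower.

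The lines were then compared for changes they shared. Genes at least 1.5-fold higher in both numbered 5, against 0.668 expected of independent lists, and 5 were lower in both, against 0.877 expected. Besides FBP1, the shared higher genes were the zinc finger gene BNC2 (log2 change 0.76 in MDA-MB231, where it was among the 19 dim genes abundant in Hs578T, and 0.90 in Hs578T), the metalloprotease gene ADAMTS1 (0.74 and 0.84), the cytokine gene IL1B (0.60 and 1.36) and the glucosidase gene MGAM (0.59 and 0.81). The shared lower genes were PLXDC2 (−0.73 and −0.82), the tryptophan catabolism gene KYNU (−0.72 and −0.87), the osteopontin gene SPP1 (−0.60 and −1.25), ZNF117 (−0.59 and −1.51) and TXNIP (−0.59 and −2.37). In MDA-MB231 the changes of IL1B, MGAM, SPP1, ZNF117 and TXNIP lay close to the 1.5-fold cut (0.585 log2), so both counts are sensitive to it. Opposite differences of this size were also counted: 7 genes were higher in MDA-MB231 and lower in Hs578T, against 0.81 expected, and 3 the reverse, against 0.724. Counts above expectation thus occurred in opposite as well as shared directions, so the excess does not by itself show a shared response. At 2-fold, 1 gene, FBP1, was higher in both, none was lower in both, and SLCO4C1 was lower in MDA-MB231 and higher in Hs578T. Across genes, which are not independent replicates, the changes in the lines correlated at r = 0.0659 and rho = 0.0357, and at r = 0.0331 without FBP1.

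**Figure D2:**
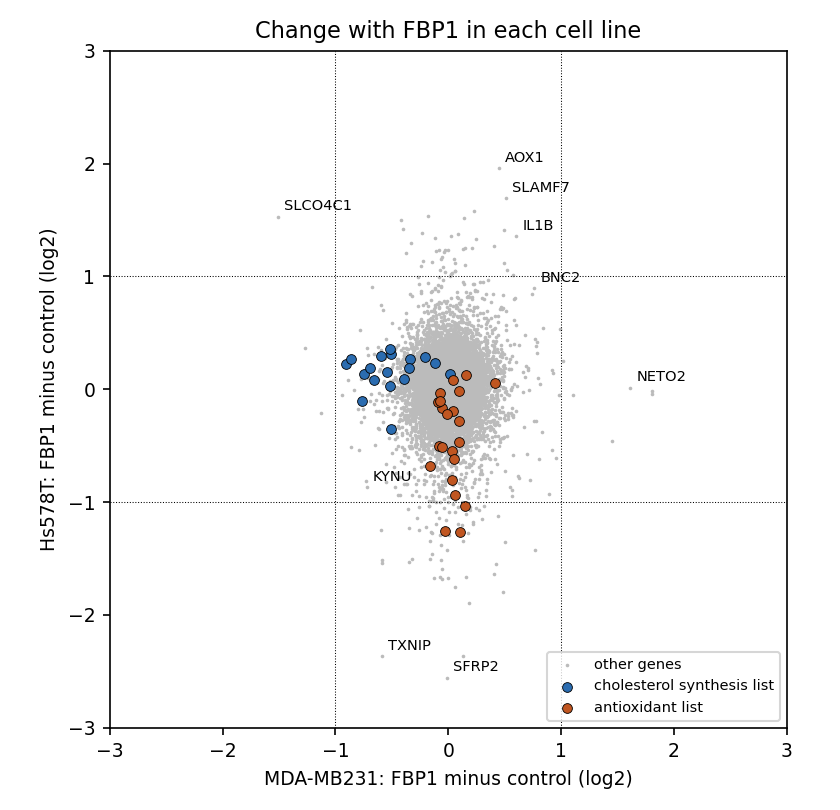
Log2 change with FBP1 in MDA-MB231 (horizontal axis) and Hs578T (vertical axis), 1 point per gene, with dotted lines at 2-fold, members of the cholesterol synthesis list in blue and of the antioxidant list in orange. FBP1, at 9.44-fold and 128-fold, lies outside the axes; the cholesterol synthesis genes lie mostly left of 0 and the antioxidant genes mostly below 0.

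With the lines as the replication, limma called 0 of 15946 genes at adjusted p under 0.05, and its smallest adjusted p was 0.943. At unadjusted p under 0.05 it gave 819 genes, against 797.3 expected by chance. The 10 genes shared at 1.5-fold, FBP1 among them, each had an adjusted p of 0.943. Since the introduced gene itself was not called, the 0 calls do not show that no other gene changed. Adjusted over the list alone, in lists fixed before the data were examined, 8 genes passed, among them FBP1, IL1B, ADAMTS1, the collagenase gene MMP13 (−0.48 and −0.69), the growth factor gene FGF5 (0.47 and 0.72) and the sterol desaturase gene SC5D (−0.51 and −0.35). The others were the histone gene H4C8 (−0.47 and −0.86) and the transcription factor gene SPDEF (−0.53 and −0.43). No adjustment was made over the 38 lists, so some of these genes may have passed by chance. FBP1 is the introduced gene, and its pass is no support. Over all genes, the limma adjusted p of each of the 8 was 0.943. The error of this fit is the difference between the FBP1 changes of the lines, moderated by the prior. Its p-values thus measure disagreement between different lines, with any technical spread included. They do not measure the spread of repeated cultures, since each line and construct has 1 array.

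Genes of lipid synthesis were mostly lower with FBP1 in MDA-MB231 and mostly higher in Hs578T, a difference that was not tested. The median log2 change of 18 cholesterol synthesis genes was −0.517 in MDA-MB231, where 17 lay below 0 and 7 were at least 1.5-fold lower. In Hs578T it was 0.191, with 16 above 0. Among them HMGCS1, the cytosolic HMG-CoA synthase, stood at −0.90 and 0.22, the squalene epoxidase gene SQLE by −0.77 and −0.10, and DHCR7, the last step to cholesterol, by −0.74 and 0.14. The 15 fatty acid synthesis genes had medians of −0.226 and 0.179, with the desaturase genes SCD (−0.62 and 0.17) and FADS2 (−0.60 and 0.35). Each median lay outside the central 95% range of random lists matched on expression. Camera on the fit over both lines gave adjusted p = 0.00182 for cholesterol synthesis, lower with FBP1, although its Hs578T median was above 0, and adjusted p = 0.757 with an estimated correlation. For fatty acid synthesis the adjusted p was 0.133.

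Antioxidant genes of the NRF2 programme were mostly lower with FBP1 in Hs578T; the difference between the lines was not tested. Their median was −0.371 there, with 19 of 22 below 0 and 7 at least 1.5-fold lower, and 0.0387 in MDA-MB231, where 13 were above 0. Both medians lay outside the matched range, the MDA-MB231 median on the higher side at percentile 98.29. The heme oxygenase gene HMOX1 stood at −0.03 in MDA-MB231 and −1.26 in Hs578T, and the aldo-keto reductase genes AKR1B10 by 0.11 and −1.27, AKR1C1 by 0.15 and −1.03 and AKR1C3 by 0.06 and −0.93. AKR1C genes are similar in sequence, and the AKR1C1 change in Hs578T was −0.40 as the mean of its probe sets. Camera gave adjusted p = 0.000109, lower with FBP1, and adjusted p = 0.757 with an estimated correlation.

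The lists of hypoxia-inducible and interferon-induced genes had medians below 0 in both lines, and the chemokine and G protein-coupled receptor list had medians above 0 in both, each outside the matched range. The 20 hypoxia genes had medians of −0.121 and −0.184, with 16 below 0 in MDA-MB231 and 18 in Hs578T, and included DDIT4 (−0.20 and −1.22), ANGPTL4 (−0.20 and −0.82), NDRG1 (−0.04 and −0.69) and the histone demethylase gene KDM3A (−0.12 and −0.66). The 25 interferon genes had medians of −0.14 and −0.0794, with IFI44 (−0.35 and −1.53), BST2 (−0.26 and −0.95), IFI44L (−0.25 and −0.64) and RSAD2 (−0.88 and 0.09). The 9 receptor list genes had medians of 0.10 and 0.427, with CXCR4 (0.17 and 0.58), PTGER4 (0.10 and 0.76), LPAR1 (0.05 and 0.73) and F3 (0.30 and 0.31), the last of them tissue factor, which is not a chemokine receptor. Camera gave adjusted p = 2.88e-05 for hypoxia, 0.00302 for interferon and 3.81e-05 for the receptor list. Each was 0.757 with an estimated correlation.

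Proliferation lists had medians of opposite sign in the lines, each outside the matched range; this difference was not tested either. The 28 S phase genes had a median of −0.0864 in MDA-MB231, or −0.056 after quantile normalization and still below the range, and 0.282 in Hs578T, where 26 were above 0, with POLE2 (−0.02 and 0.68), UHRF1 (−0.08 and 0.49) and GINS1 (0.04 and 0.47). The 25 G2 and M phase genes had medians of −0.123, with 23 below 0, and 0.119, with 20 above 0, and included CENPE (−0.29 and −0.07), TTK (−0.29 and 0.00) and PTTG1 (0.00 and 0.39). Camera gave adjusted p = 0.0389 for S phase, higher with FBP1 despite the MDA-MB231 median, and 0.835 with an estimated correlation. For G2 and M phase the adjusted p was 0.529.

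In MDA-MB231 alone, 6 further lists lay outside the matched range. They were the pentose phosphate pathway (0.157), the TCA cycle (0.0486), inflammation (0.112, with IL1A at 0.67 and IL1B at 0.60), histone genes (−0.294, with H4C8 at −0.47 and H2BC12 at −0.46), collagen and matrix (−0.0823, with LUM at −1.13 and POSTN at −0.78) and basal keratins (−0.13). The histone list did not hold H2BC7 or H4C5. In Hs578T alone, 6 others did so: mitochondrial ribosome (0.108, with MRPL1 at 0.44), growth factors and receptors (0.179, with NRG1 at 0.90), antigen presentation, a list of HLA genes and of genes such as B2M that act with them (−0.147, and −0.237 with probe sets of a gene averaged, with HLA-DPA1 at −1.09), p53 targets (−0.111, with TP53INP1 at −0.91), ATF4 and unfolded protein response (−0.145, with TRIB3 at −0.69) and fatty acid oxidation (−0.104, with PDK4 at −0.74). The last was inside the range without the probe set filter (−0.035), and p53 targets were inside it without members that other lists hold (−0.031). Camera with the preset correlation called inflammation (adjusted p = 0.00834), histone genes (0.000427), mitochondrial ribosome (0.0266), growth factors (0.0266) and ATF4 (0.000102), and gave each an adjusted p of 0.757 with an estimated correlation. Outside the range were 14 lists in each line, against 1.9 of 38 expected if genes varied independently. Members of a list can vary together, and where they do, 1.9 is too low as a chance count. Estimated correlations were 0.84 for G2 and M phase and 0.725 for S phase. With 1 residual degree of freedom, these reflect only how many members differ between the lines in the same direction. They are no separate evidence that members vary together. The test fry called 0 lists, with a smallest adjusted p of 0.619.

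The lists of glycolysis, gluconeogenesis, respiratory chain complexes and epithelial-mesenchymal transition lay inside the matched range in both lines. The pentose phosphate and TCA cycle lists lay above it in MDA-MB231 (0.157 and 0.0486), as given above. Glycolysis genes had medians of 0.00095 and −0.0116, with HK2 at 0.44 and −0.01 and the glucose transporter gene SLC2A3 at 0.07 and −0.96. The 6 gluconeogenesis genes, FBP1 included, had medians of 0.0655 and 0.117. Complex I genes of the respiratory chain had medians of 0.0195 and 0.00705, and those of complexes III to V 0.0062 and 0.0204. Of 23 epithelial-mesenchymal transition genes, 0 differed by 1.5-fold in either line, and the medians were 0.0352 and 0.0024. CDH1, which encodes E-cadherin, stood at 0.25 and −0.19, VIM by −0.01 and 0.00, SNAI1 by −0.15 and −0.11 and ZEB1 by 0.17 and 0.15. With probe sets of a gene averaged, this list lay above the range in MDA-MB231 (0.078). Without members that other lists hold, its medians were −0.005 and 0.102, both inside the range. A list of 17 genes linked to FBP1 in work on such cells had medians of 0.01 and 0.0792, with the mitochondrial transcription gene TFB1M at 0.17 and 0.41. Without members that other lists hold, an alternative chosen after the data were seen, it lay just above the range in Hs578T (0.153, percentile 97.51). Since that list comes from the study's own subject, it is not independent evidence.

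The remaining lists inside the range in both lines were Wnt targets (−0.0233 and 0.0239, with DKK1 at −0.06 and 0.77), stem cell genes (−0.0164 and 0.0931), TGF-beta targets (0.0212 and −0.0531), glutamine and amino acid metabolism (−0.007 and −0.00808), proteases (−0.0064 and −0.0591), integrins and adhesion (0.0462 and 0.0872), early response genes (−0.0169 and −0.00865) and housekeeping genes (−0.0061 and −0.0177). Without members that other lists hold, TGF-beta targets lay below the range in Hs578T (−0.229). The stem cell median in MDA-MB231 turned to 0.072 with probe sets of a gene averaged and 0.079 without the probe set filter, both inside the range. Among markers of other cell types, medians were 0.0322 and 0.0928 for luminal epithelium, 0.0845 and 0.0685 for leukocytes, 0.0385 and 0.0737 for endothelium and 0.06 and 0.0445 for fibroblasts. The fibroblast median in MDA-MB231 was 0.134 without members that other lists hold, inside the range. FAP, a fibroblast marker, stood at 0.13 and −1.34.

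**Figure D3:**
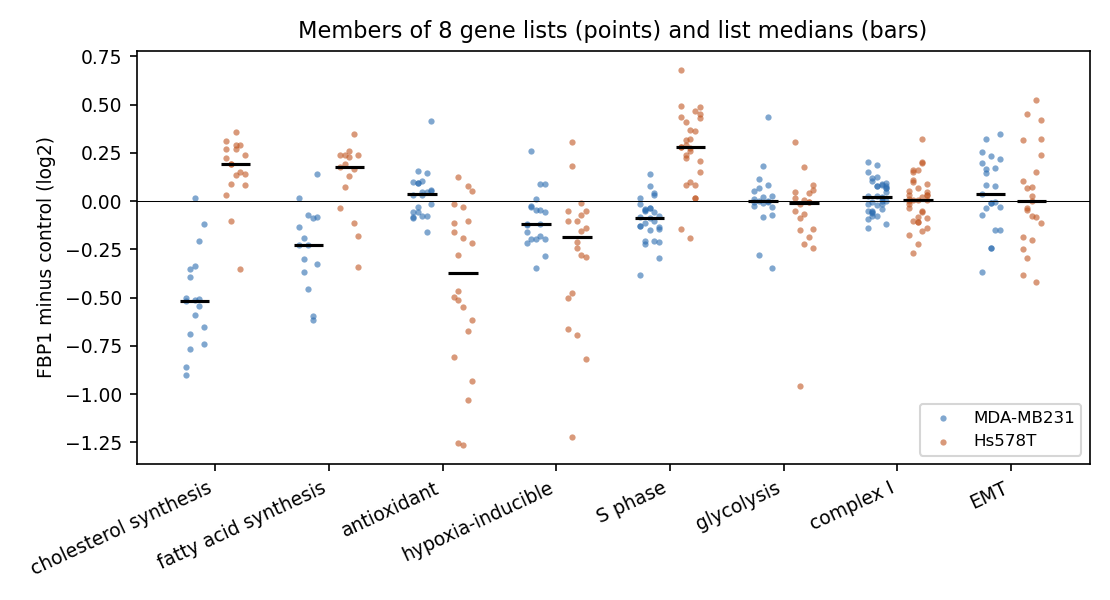
Log2 change with FBP1 (vertical axis) of the members of 8 gene lists, 1 point per gene, in MDA-MB231 (blue) and Hs578T (orange), with bars at the list medians. Cholesterol synthesis stands at −0.517 and 0.191, antioxidant genes at 0.0387 and −0.371, and S phase genes at −0.0864 and 0.282.

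The other factor of the design was the cell line. MDA-MB231 and Hs578T differed widely, with 6500 genes (40.8%) called by limma, of which 3475 were higher in MDA-MB231 and 3025 in Hs578T. Among the 12 largest measured differences in favour of MDA-MB231 were the annexin gene ANXA3 (6.87 log2), the lysosomal membrane gene LAPTM5 (6.47), the urea transporter gene SLC14A1 (6.34), RFPL4A (5.77), TNFSF10 (5.75), which encodes the death ligand TRAIL, and the lipid droplet gene PLIN2 (5.70). CD96, PLAC8, CDCP1, SERPINB9, QNG1 and PDE8B followed, at 5.35 to 4.98. Higher in Hs578T were the matrix genes VCAN (−6.91) and POSTN (−6.59), NETO2 (−6.10), the cadherin gene CDH6 (−5.99), H2BC7 (−5.98), DSEL (−5.80) and CD109 (−5.76). Copies of the small nucleolar RNA SNORD116 made up 5 of the 12 largest differences towards Hs578T and 6 of 6 measured copies were called higher in Hs578T, with a median of −6.24. SNORD116-14, SNORD116-20, SNORD116-21 and SNORD116-24 lay below the filter level in MDA-MB231 and passed only through Hs578T. Copies low in both lines were left out, so the 6 of 6 is partly set by the filter. Some of these genes were dim in the line with the lower value, such as SNORD116-14 and ANXA3, both below the filter level of 6.16 there, so the sizes and order of such differences are uncertain. Standard errors of the named differences lay between 0.10 and 0.38, and the limma adjusted p was 4.49e-06 for ANXA3 and 3.68e-06 for VCAN. The fit counted a line's control and FBP1 arrays as its replicates (n = 2 arrays per line). The construct term removed the FBP1-minus-control difference common to both lines. Clone and culture differences that were not alike in both lines entered the error.

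By list, 23 of 27 collagen and matrix genes were higher in Hs578T and 4 in MDA-MB231, with a median difference of −1.44, and 14 of 15 fibroblast markers were higher in Hs578T (−3.47). TGF-beta targets (−0.904, with 14 of 21 higher in Hs578T) and ATF4 targets (−0.499, with 19 of 27) stood the same way. Higher in MDA-MB231 were 19 of 25 interferon genes (median 1.08), 9 of 11 genes of the antigen presentation list (0.933), 10 of 20 glycolysis genes (0.285), 12 of 25 G2 and M phase genes (0.302) and 9 of 15 luminal markers (0.495). Camera called these 9 lists with the preset correlation, with adjusted p from 1.43e-09 for collagen and for fibroblast markers to 0.0091 for luminal markers. With an estimated correlation it called 0, with an adjusted p of 0.856 as the smallest, but that run rests on 1 residual degree of freedom and could hardly call any.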

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

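The tests of intensity bias and of culture or clone were chosen after the results were seen; the tests of the second gene lists were written before their results. Differences between the lines' changes were not tested, since 1 array per group leaves no residual degree of freedom. Results are listed here because the lines moved in opposite directions. SLCO4C1 changed by −1.51 in MDA-MB231 and 1.53 in Hs578T, where its control value (6.29) was not shown to be above background. The list medians were −0.52 and 0.19 for cholesterol synthesis, −0.23 and 0.18 for fatty acid synthesis, 0.04 and −0.37 for antioxidant genes, −0.12 and 0.12 for G2 and M phase genes and −0.09 and 0.28 for S phase genes.

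For cholesterol synthesis in MDA-MB231, an intensity-dependent bias between the arrays would shift matched random lists as far. The list lay at percentile 0 of them, with deposited values and after quantile normalization. The same kind of comparison had already placed this list outside the matched range, so it is no separate test of such a bias. A second list of 14 sterol-regulated genes that shares no gene with any fixed list had a median of −0.17, with 13 below 0 and at percentile 0, which is consistent with lower sterol-regulated transcription in that array. In Hs578T the second list had a median of 0.0845. With 1 array per culture, an effect of FBP1 and another difference between the cultures or clones, such as cell density, cannot be told apart.

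For antioxidant genes in Hs578T, the list likewise lay at percentile 0 of matched lists under both scalings. This too repeats the comparison that placed the list outside the matched range, and is no separate test of an intensity-dependent bias. A second list of 23 NRF2 target genes, sharing none with the fixed lists, had a median of −0.11, with 17 below 0 and at percentile 0.55, which is consistent with lower NRF2 activity in that array. In MDA-MB231 the second list was at 0.0795, percentile 99.8. An effect of FBP1 and a difference between cultures or clones cannot be told apart here either, with 1 array per culture.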

How the results depend on the processing

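No named-gene change of at least 2-fold and no list median outside the matched range turned sign under the alternatives run. Values near 0 did: 9 named-gene changes, each at most 0.05 in size, and 14 values of 11 list medians, each at most 0.035 in size, among them stem cell genes, epithelial-mesenchymal transition (−0.005) and TGF-beta targets (−0.012) in MDA-MB231. Over 9 alternatives limma called 0 genes or probe sets for FBP1, with 575 to 966 genes at unadjusted p under 0.05 where the cell line block was kept and 38 without the block, which pairs the arrays of a line. The line comparison gave 2968 to 3505 genes higher in MDA-MB231 and 2630 to 3118 higher in Hs578T. With all probe sets fitted, named or not, the counts were of probe sets: 1306 at unadjusted p under 0.05 for FBP1, and 4597 higher in MDA-MB231 and 3592 higher in Hs578T. The FBP1 change stayed at 3.23 to 3.25 in MDA-MB231 and 6.99 to 7.03 in Hs578T. At 1.5-fold in place of 2-fold, by construction, 48 genes were higher and 52 lower in MDA-MB231, 222 higher and 269 lower in Hs578T, 5 higher in both and 5 lower in both. The 50th percentile filter, which tests fewer genes, left 43 lower in Hs578T (73 before). Leaving out genes at least 16-fold more abundant in Hs578T, chosen after the data were seen, left 3 higher in MDA-MB231 (7 before). With an estimated correlation, camera called 0 lists for FBP1 (11 before) and 0 for line (9 before). With 1 residual degree of freedom it could hardly call any, so this does not decide whether the preset calls hold. Of named-gene changes, 2126 values moved by less than the gene's moderated standard deviation in the limma fit and 20 by more, 10 by averaging probe sets and 10 by taking 1 line alone, which leaves no test. Of list medians, 286 moved by less than the spread of matched random lists and 18 by more. Signal over background was not used here, so for dim genes a difference near background can be understated.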

Other observations

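The tests of carry-over and of dim probe sets were chosen after the result was seen, and the genes in the next paragraph after their values were seen.

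The clustered protocadherin beta genes, cell adhesion molecules encoded side by side, were lower together in Hs578T with FBP1. Of 17 measured, 16 were at least 1.5-fold and 13 at least 2-fold lower, with a median log2 change of −1.14 and a range of −1.69 to −0.564. In MDA-MB231 the median was −0.145 and 0 were 1.5-fold lower. The 11 measured protocadherin alpha genes had an Hs578T median of 0.00514, with 1 at least 1.5-fold lower, and the 1 measured protocadherin gamma gene stood at 0.733. Members share sequence and probes can bind several of them, so single values are uncertain. The counts are uncertain too, since the 17 genes may not be independent readings. ARRDC4, a paralogue of TXNIP that responds to the same glucose-sensing factors, changed by −0.05 in MDA-MB231 and −0.82 in Hs578T, beside −0.59 and −2.37 for TXNIP.

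Of the 6 genes besides FBP1 that were at least 2-fold higher in MDA-MB231 with FBP1, 4 (H2BC7, H4C5, NETO2 and KLHL9) were far more abundant in Hs578T. Carry-over of Hs578T RNA into that sample would bring every abundant Hs578T transcript, at a share of 1.72% or more by these genes. Of 44 transcripts abundant in Hs578T and scarce in MDA-MB231, these 4 included, 35 stayed below the level that share needs. Of the 35, 18 were below control, among them POSTN (−0.78) and LUM (−1.13). The 4 genes set the share and so reach the level by construction. ACTA2, FKBP10, GPNMB, H4C4 and SH3BGRL also reached it. The share takes intensity as proportional to RNA, which was not checked. The 4 genes were picked for their increase, which can inflate the share, and the median share over the 44 transcripts was 0.239%. The 35 thus argue only against carry-over at 1.72% or more as the sole cause of these 4 changes. Noise of dim probe sets is argued against by genes at the same control level (5.14 to 5.80 log2) that were not abundant in Hs578T, taken without the probe set filter: 1 of 964 (0.104%) was at least 2-fold higher, and 95% of them lay between −0.372 and 0.408. Genes at that level that were abundant in Hs578T were mostly above control, 14 of 15 without the 4 genes, with a median of 0.267, so a smaller share of Hs578T RNA stays open. No biological explanation was tested.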
